A study of Drosophila melanogaster with 2 samples.

How the data were processed

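Chromatin immunoprecipitation with sequencing (ChIP-seq) was performed on whole Drosophila melanogaster embryos aged 0 to 24 hours, of both sexes, from a transgenic line that carries the zinc finger protein CG1792 fused to green fluorescent protein (GFP). Per the labels, chromatin was sheared by sonication and precipitated with an antibody against GFP, although a separate antibody field names CG1792 itself. The 2 libraries, biological replicates 2 and 3, formed 1 group, and no control library was among the samples, so no contrast between conditions could be made.

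The values were peak lists that the authors made for the genome builds dm6 and dm3. Per the library listing deposited with the samples, regions were called against a control alignment in each replicate and in the pooled replicates as lists of peaks and background, and a final list was thresholded by the irreproducible discovery rate, a measure of how well region ranks repeat between replicates. The aligner, the peak caller, their versions and the filters are not given in the sources used here. The deposited signal value is the strength of a region as the caller wrote it. Its scale is not stated and differs between lists, so signals were compared within a list or by rank. Exceptions were the ratio, Pearson's r and scatter of the signals of the replicates. The level of that ratio and the line of equal signal depend on scale, so neither is read as a difference between libraries. The −log10 q-value of each region, deposited beside the signal, was not used in any test. The deposited offset of each summit from the region start gave the summit position. Every deposited single-replicate and pooled list held 30000 regions, and the thresholded lists held 2892 regions in dm6 and 2875 in dm3. The control alignment and the signal tracks were not analysed here. The lists hold no read counts, so the depth of each library is unknown and no interval that needs depth is given. The confidence intervals cover the counting of peaks, genes or windows only.

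All positions are in dm6, 1-based, and were checked to lie within the chromosome lengths of the reference genome. Genes came from the Ensembl annotation of BDGP release 6, Ensembl release 115, with 13945 protein-coding genes on chromosome arms X, 2L, 2R, 3L, 3R and 4. The dm3 lists were used for counts and replicate overlap only. A gene was called bound when a summit of the thresholded list lay within 500 bp of any of its annotated transcript starts, and 1 summit could mark several genes. The background set was the 26452 pooled regions that did not overlap a thresholded peak, which were measured in the same libraries. A summit within 500 bp of any gene start counted as promoter; other summits were assigned to exons, introns or the space between genes.

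Replicate overlap was the share of the 2892 strongest regions of one replicate with a summit of the other's 2892 strongest within 100 bp, set against 100 shuffles of positions along each chromosome (one-sided permutation test). Shares were compared by two-sided Fisher's exact tests with Wilson 95% intervals; the promoter share was also set against 1000 draws of random positions on the same chromosomes (one-sided permutation test). Median signals were compared with a two-sided permutation test of 100000 resamples. Bound members of 20 gene lists were compared with all other protein-coding genes by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over the 20 lists. Where no member was bound, the limit that a count of 0 allows was taken as 3 genes of the list. The lists covered cytoplasmic and mitochondrial ribosomal proteins, translation factors, proteasome, respiratory chain, splicing, replication and cell cycle, insulator proteins, genes with a zinc-finger associated domain (ZAD, the N-terminal domain of CG1792's family), Hox, segmentation and signalling genes, Polycomb and trithorax genes, markers of neurons, muscle, germline and haemocytes, heat shock, chemoreceptor and cuticle genes. The presence of 12 consensus elements and of all 8192 canonical 7-mers in the 101 bp around each summit was compared with a window of equal size 300 bp away by an exact two-sided McNemar test, or with unbound starts by two-sided Fisher's exact tests, with Benjamini-Hochberg adjustment over each family. A threshold of 0.05 was applied throughout.

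The rule for named genes took the 25 protein-coding genes at the strongest thresholded peaks found among the 2892 strongest regions of both replicates, up to 3 bound members of each list past the threshold, at most 1 bound member of each other list, and CG1792 itself. The tests of replicate overlap, promoter share, promoter signal, the X chromosome, gene lists and motifs, the gene lists, the consensus elements, this rule and the first alternatives below were fixed before the data were examined. Alternatives were a window of 250 or 1000 bp, the stronger 1446 peaks, other backgrounds, assignment of each summit to its nearest start only, other overlap criteria, and leaving out each replicate by taking the 2892 strongest regions of the other. A null drawn from each replicate's own regions, windows shuffled with their dinucleotide counts kept, gene lists with CG1792 left out, the peaks at protein-coding starts against their flanks, and peak ranks of the named genes within each replicate were added after seeing the data, as were the tests of upstream position, of features away from starts (two-sided Fisher's exact, adjusted over 6 features) and of ATCGATA at starts against elsewhere, and the comparison of peak ranks by replicate partner. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. On simulated data, random windows gave 0 of 8192 7-mers past the threshold, and 19 of 20 7-mers planted in 2% of windows were recovered. These windows lay at random positions and lacked the lower GC content of real summits, so calls that stem from base composition were not covered. With genes bound at random, 2 of 50 simulations called any gene list. With lists bound at 30%, 11 of the 20 were recovered, and at 60%, 19 of the 20. Simulated genes were bound independently of each other, whereas in the data 1 summit could mark several genes.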

Results

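Binding of CG1792, a C2H2 zinc finger protein of the ZAD family, was mapped by ChIP-seq in 2 biological replicates of whole embryos that expressed a GFP fusion of the protein. The thresholded list held 2892 peaks in dm6, and these were exactly the 2892 strongest of the 30000 pooled regions. Peak signals ran from 66.97 to 1589, with a median of 100.6, and 2427 of the peaks had the common width of 416 bp. The large arms carried 20.95 to 23.3 peaks per Mb, with 696 peaks on 3R, 589 on 3L, 548 on 2L, 539 on 2R and 512 on X. Chromosome 4, which is largely heterochromatic, carried 8 peaks, or 5.93 per Mb, although it had 299.7 background regions per Mb against 177.0 to 211.3 on the large arms. The depth of the libraries is unknown.

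The first question was how far the replicates marked the same sites. Of the 2892 strongest regions of each replicate, 1923 (66.5%) had a summit of the other within 100 bp, against a mean of 13.11 and a maximum of 21 in 100 shuffles (permutation p = 0.0099, the smallest these shuffles can give). Random regions drawn from the 2 lists themselves, an alternative chosen after seeing the data, shared 94.19 on average and at most 124. The share with a partner was 98.6% in the strongest 10% of these regions in replicate 2 and 99.3% in replicate 3, and 30.3% and 28.6% in the weakest 10%. Of the thresholded peaks, 1945 (67.3%) were among the 2892 strongest regions of both replicates, and 2753 had a summit in both complete lists. Over these 2753 peaks the signals of the replicates had a Spearman correlation of 0.668 (95% interval 0.647 to 0.688), which is across peaks that are not independent replicates. The thresholded list was itself cut by how well ranks repeat between these replicates, so agreement over its peaks is partly built in. The log2 ratio of replicate 3 to replicate 2 had a median of 0.21 and an SD of 0.52 over the same peaks. Its median depends on the unstated signal scales of the 2 lists and is not read as a difference in level.

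**Figure D1:**
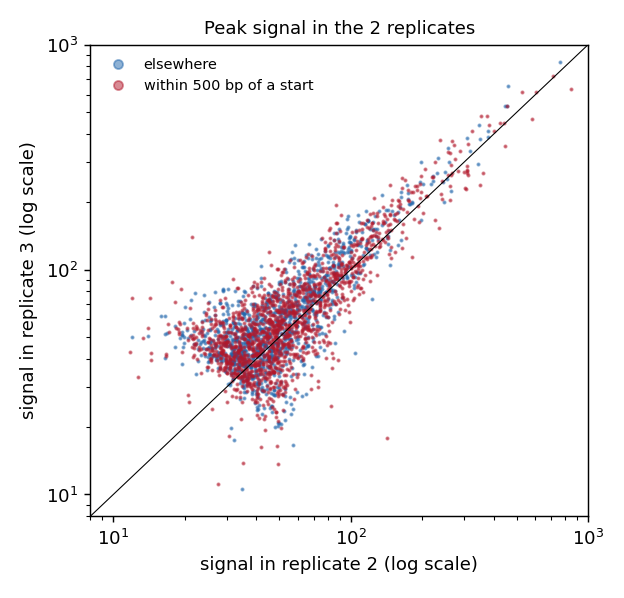
Signal of each thresholded peak in replicate 2 (horizontal, log scale) against replicate 3 (vertical, log scale), red within 500 bp of a gene start and blue elsewhere, with the line of equal signal. The signal scales of the lists are not stated, so distance from this line is not read as a difference in level. Over 2753 peaks the Spearman correlation was 0.668, and the scatter widens among the weaker peaks.

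The strongest peak of all lay in an intron of ush, which encodes a cofactor of GATA transcription factors, on 2L at 480880 to 481304 (signal 1589; 761 in replicate 2 and 833 in replicate 3). The second marked the start region shared by DUBAI, a deubiquitinase gene, and Tmem18 on 2R (12435667 to 12436230, signal 1478), and it ranked 1 in replicate 2 and 4 in replicate 3. It was followed by Ugalt, a UDP-galactose transporter gene on X (2703677 to 2704093, signal 1429, summit 33 bp outside the gene), by CG14100 on 3L (19590440 to 19590807, signal 1214) and by an internal start of px, a wing vein gene on 2R (22514113 to 22514501, signal 1139). Smg5, a nonsense-mediated decay gene on 2L, ranked 7 with a signal of 1049. The peak of rank 11 (signal 892) lay in the 5′ UTR of Chro, which encodes the chromosomal protein Chromator, 200 bp from the start of Ssl1, a gene for a TFIIH subunit.

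The next promoter peaks by strength included mRpL41 (rank 12, signal 876), PNPase (rank 13, signal 856), the arginine methyltransferase gene Art3 together with mRpS10 (rank 14, signal 834), Mic26-27 together with CG5916 (rank 17, signal 804) and CenG1A together with mRpS23 (rank 22, signal 736). The rest of the 25 genes at the strongest promoter peaks were CG1888 (rank 15), CG31145 (rank 24), the casein kinase gene gish (rank 26), CG9147 with Fbw5 (rank 28), CG10555 (rank 29), Mnat9 with CG1792 (rank 30) and larp (rank 31). In the single replicates these peaks ranked between 1 and 60.

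CG1792 was thus itself among these genes. The peak lay on 3R at 31616014 to 31616323, with its summit at 31616147, in the 5′ UTR of the divergent gene Mnat9 and at −156 bp from the start of CG1792 (FBgn0039860, 31616303 to 31617837). Its signal was 620.7 in the pooled list, 287 in replicate 2 (rank 37) and 337 in replicate 3 (rank 29). The flies also carried the fusion gene, and whether it includes this promoter is not given in the sources used here.

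Strong peaks away from protein-coding starts, chosen after their values were seen as those found among the strongest regions of both replicates, lay in introns of CG11050 (rank 6, signal 1113), of the kinase gene Lk6 (rank 8, signal 990), of the Polycomb group gene ph-p (rank 10, signal 977, at −501 bp from the nearest start), of CG9663 (rank 18, signal 788), of CG32772 (rank 21, signal 738) and of cno, a gene of cell junctions (rank 23, signal 698). Others lay at the long noncoding RNA genes CR31840 (rank 9, signal 983) and Vinr (rank 16, signal 815) and in an exon of a further one, CR44619 (rank 25, signal 653). Between genes lay a peak on 2R (rank 19, signal 786) and another on 3R (rank 20, signal 766).

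The next question was where in genes the peaks lay. Gene starts held 1608 of the 2892 summits within 500 bp, or 55.6% (Wilson 95% interval 53.8% to 57.4%), against 7615 of 26452 background regions, or 28.8% (odds ratio 3.10, two-sided Fisher's exact p = 3.98e-177). Random positions on the same chromosomes gave 13.6% ± 0.644 (SD of 1000 draws), 4.08-fold less (permutation p = 0.001, the smallest these draws can give). The share was 59.2% in the strongest 723 peaks and 52% to 56.3% in the 3 sets of 723 peaks that followed. The replicates taken alone gave 54.6% without replicate 2 and 56.0% without replicate 3.

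Peaks at protein-coding starts sat on the upstream side. Of 1534 summits within 500 bp of the nearest such start, 1219 (79.5%) lay upstream, with a median position of −82 bp and quartiles of −167 and −16 bp. Background regions in the same window were upstream in 50.2% of cases, with a median of −1 bp (two-sided Fisher's exact p = 6.46e-103).

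**Figure D2:**
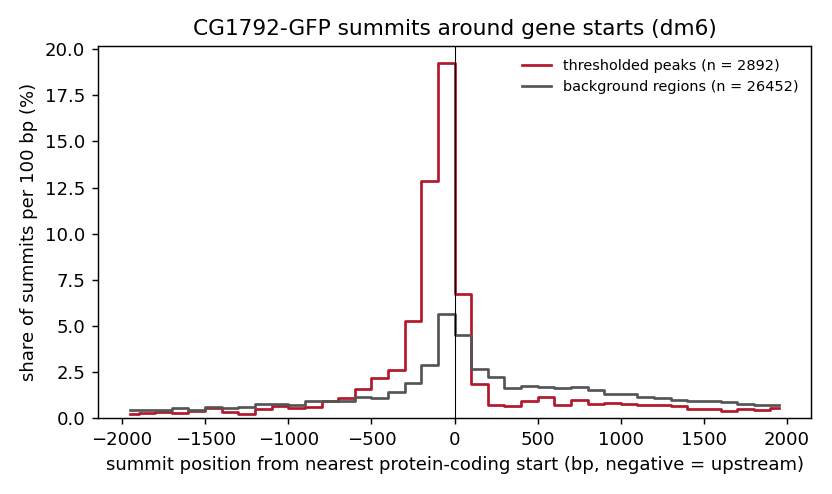
Share of summits per 100 bp (vertical, percent) by position from the nearest protein-coding start (horizontal, bp, negative upstream), for the 2892 thresholded peaks in red and the 26452 background regions in grey. The highest bin holds 19.2% of the peaks, in the 100 bp upstream of starts, against 5.62% of the background regions.

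Over all 2892 peaks, introns held 31.5% against 39.0% of background regions (odds ratio 0.717, two-sided Fisher's exact, adjusted exact p = 1.46e-15) and the space between genes 10.4% against 15.6% (odds ratio 0.632, adjusted exact p = 4.02e-14), both fewer. Among peaks away from starts, introns held 910 of 1284 peaks (70.9%), more than the 54.8% of background regions there (odds ratio 2.00, two-sided Fisher's exact, adjusted exact p = 1.14e-29). Coding exons held 8 of the 1284 peaks (0.623%) against 15.0% of background regions (odds ratio 0.0355, adjusted exact p = 3.06e-73). The 3′ UTRs held 23 peaks, or 1.79%, also fewer than the 5.11% of the background (odds ratio 0.339, adjusted exact p = 5.63e-09). The space between genes held 302 of these peaks (23.5% against 21.9%, adjusted exact p = 0.261), which did not pass the test.

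Peaks at gene starts were little stronger than the others. Their median signal was 102.9 in 1608 peaks and 97.95 in the other 1284, a ratio of 1.05 (two-sided permutation p = 0.0296). The difference did not pass the test with a window of 250 bp (ratio 1.01, permutation p = 0.757) or without replicate 2 (ratio 1.02, permutation p = 0.198).

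In all, 1981 of 13945 protein-coding genes (14.2%) were bound at a start. Genes of X, which occurs once in males and as a pair in females of these mixed embryos, were bound less often than other genes, 276 of 2196 (12.6%) against 1705 of 11749 (14.5%; odds ratio 0.847, two-sided Fisher's exact p = 0.0165). With a window of 1000 bp this difference did not pass the test (odds ratio 0.907, exact p = 0.133). The share also varied among the other large arms, from 13.4% on 2R to 15.9% on 3R. X had 177.0 background regions per Mb, the fewest of the large arms. On chromosome 4, 4 of 80 genes (5.0%) were bound. Among other gene classes, 143 of 3261 ncRNA genes (4.39%), 8 of 290 tRNA genes and 7 of 269 snoRNA genes had a summit at a start.

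Which kinds of gene were bound was asked with 20 lists, and 8 differed from other genes, 6 of them higher and 2 lower. Cytoplasmic ribosomal protein genes stood furthest out, with 55 of 88 bound (62.5%) against 13.9% of other genes (odds ratio 10.3, 95% interval 6.57 to 16.5, two-sided Fisher's exact, adjusted exact p = 3.40e-24). The strongest were RpS27 (3R, signal 443, rank 72), RpL7 (2L, signal 382, rank 96) and RpL14 (3L, signal 322, rank 129), with summits at −22, 35 and −41 bp from the start. Of the 55 summits, 38 lay in the 100 bp upstream of the start, with a median position of −28 bp over all 55. Reads of RpS14b, another bound member, could be shared with its near-identical copy RpS14a, so that peak is uncertain. The list passed the test in each of the 8 alternative settings, with odds ratios from 5.51 to 13.2.

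Genes of chromatin architecture and Polycomb or trithorax regulation were also bound more often than other genes. Of the insulator and architectural genes, 10 of 21 (47.6%) were bound (odds ratio 5.51, two-sided Fisher's exact, adjusted exact p = 0.00120), led by Chro (signal 892), pzg (signal 499) and Trl, the gene of the GAGA factor (signal 199). The bound members included Cp190 (signal 181), Dref (132, a peak shared with RpL13), M1BP (83.3), BEAF-32 (83.0), Clamp (79.9), pita (75.8) and CTCF (70.5). The lowest signal of any thresholded peak was 66.97. CTCF and Clamp ranked outside the 2892 strongest regions of replicate 2, and BEAF-32 and pita outside those of replicate 3. In the Polycomb and trithorax list, 11 of 25 genes (44.0%) were bound (odds ratio 4.77, adjusted exact p = 0.00120), among them Su(z)12 (signal 286), Trl, ph-p (signal 144), brm (136), Psc (90.9), E(z) (74.2) and esc (73.3). Psc and esc ranked outside the 2892 strongest regions of replicate 2, and E(z) outside those of replicate 3. The ZAD list was a selection of named genes from CG1792's own family and gives no share for the family as a whole. Of its 16 genes, 6 (37.5%) were bound (odds ratio 3.63, adjusted exact p = 0.0468), with Sry-delta (signal 160) and Phs (signal 135) after CG1792. Trl, M1BP and pita each recur in a pair of these lists, so the lists are not independent. With CG1792 left out, whose peak could include copies of the fusion gene, 5 of 15 ZAD genes were bound and the list did not pass (odds ratio 3.03, adjusted exact p = 0.112). The ZAD list kept its call in 1 of the 8 alternative settings, that without replicate 2 (odds ratio 3.78, adjusted exact p = 0.0446); elsewhere its adjusted exact p ran from 0.0683 with the nearest start only to 0.263 among genes with a pooled region, and was 0.149 without replicate 3 (odds ratio 2.72). The insulator and the Polycomb and trithorax lists lost theirs in the stronger 1446 peaks (odds ratios 3.81 and 3.05, adjusted exact p = 0.0611 and 0.0932) and among genes with a pooled region (odds ratios 3.44 and 2.33, adjusted exact p = 0.0806 and 0.242).

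Heat shock genes were bound in 8 of 25 cases (32.0%, odds ratio 2.85, two-sided Fisher's exact, adjusted exact p = 0.0468), with Hsp27 (signal 247), Hsp83 (signal 199) and Hsp26 (signal 155) the strongest. With CG1792 left out, the adjusted exact p was 0.0533 for heat shock and for mitochondrial ribosomal protein genes, and both calls were lost at unchanged odds ratios. The heat shock call was also lost without replicate 2 (odds ratio 2.45, adjusted exact p = 0.142) and without replicate 3 (odds ratio 1.497, adjusted exact p = 0.602), and of the 8 alternative settings it was kept only with 1000 bp (adjusted exact p = 0.0489). Hsp22 and Hsp67Bc share 1 peak. Mitochondrial ribosomal protein genes were bound in 18 of 73 cases (24.7%, odds ratio 1.99, adjusted exact p = 0.0468), led by mRpL41, mRpS10 and mRpS23. This call was kept with either replicate left out and also lost with 250 bp (adjusted exact p = 0.0716), with 1000 bp (0.177) and in the stronger peaks (0.156). With each summit given only to its nearest start, 6 of the 73 were bound and the direction turned (odds ratio 0.764, adjusted exact p = 0.798).

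Chemoreceptor and cuticle protein genes were bound less often than other genes. Of 179 chemoreceptor genes, Ir60e alone was bound (signal 106), or 0.559% against 14.4% of other genes (odds ratio 0.0334, two-sided Fisher's exact, adjusted exact p = 7.36e-10). Of 120 cuticle protein genes 0 were bound, which allows a share of up to 2.5% (adjusted exact p = 1.18e-07).

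The other 12 lists did not pass the test. Replication and cell cycle genes came closest, with 11 of 40 bound (adjusted exact p = 0.0506), dpa the strongest at a signal of 208, and they passed without replicate 3 (odds ratio 2.89, adjusted exact p = 0.00939). Translation factors, led by eIF6 (signal 560), were bound in 12 of 53 cases and also passed without replicate 3 (odds ratio 2.60, adjusted exact p = 0.00939). Splicing factors were bound in 8 of 29 cases (Cdc5, signal 165; odds ratio 2.31, and 1.25 without replicate 3), proteasome genes in 7 of 48 (Rpn5, signal 144, with no partner in replicate 2) and respiratory chain genes in 11 of 86 (ND-MWFE, signal 213). Among developmental genes, binding was found at 5 of 40 signalling genes (spi, signal 283), 2 of 30 segmentation genes (cnc, signal 114) and 0 of 8 Hox genes, which allows up to 37.5%. Of the cell type markers, 4 of 27 muscle genes (Msp300, signal 256.4), 1 of 27 neuronal genes (elav, signal 265), 2 of 21 germline genes (bgcn, signal 195) and 0 of 18 haemocyte genes (up to 16.7%) were bound. The haemocyte list includes ush, whose intronic peak was the strongest of all. That peak lay at −1392 bp from the nearest protein-coding start, outside the window. With a window of 1000 bp, or without replicate 2, 1 of the 18 haemocyte genes was bound.

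Fewer lists passed against a narrower background. Among the 7414 genes with any pooled region at a start, of which 26.7% were bound, the cytoplasmic ribosomal protein genes alone passed the test (55 of 83, 66.3%, odds ratio 5.51, two-sided Fisher's exact, adjusted exact p = 8.51e-13). Fewer members could be tested there, such as 14 chemoreceptor, 15 cuticle and 14 heat shock genes. The odds ratios of the other lists that lost the call were 3.67 for heat shock and 0 for cuticle genes (adjusted exact p = 0.0806 each), 3.30 for ZAD and 0.211 for chemoreceptor genes (0.263 each) and 1.18 for mitochondrial ribosomal protein genes (0.658).

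**Figure D3:**
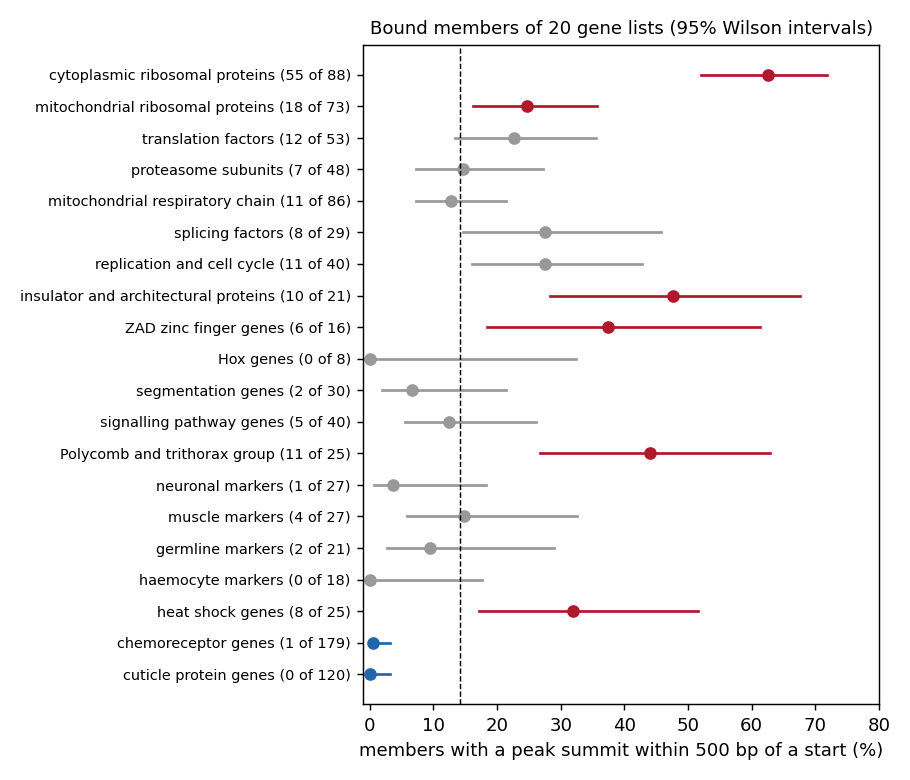
Share of members of each of the 20 gene lists with a summit within 500 bp of a start (horizontal, percent), with Wilson 95% intervals; red lists were higher and blue lists lower than other genes, grey lists did not pass the test, and the dashed line marks the 14.2% of all protein-coding genes. Cytoplasmic ribosomal protein genes reach 62.5%, and chemoreceptor and cuticle genes lie under 1%.

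The last question was which sequences lay under the summits. The DNA replication-related element (DRE, TATCGATA), a core promoter element bound by Dref, was present in 78 of 2892 summit windows (2.70%) and 0.415% of the flanking windows, 6.50-fold more (exact two-sided McNemar test, adjusted exact p = 6.30e-13); without replicate 3 it was 4.1-fold. The core promoter element Ohler 7 was present in 4.08% against 1.00% (4.07-fold, adjusted exact p = 4.67e-13), and the shorter CGATA in 18.8% against 12.5% (1.51-fold, adjusted exact p = 9.62e-11). Ohler 1, the site of M1BP, was 2.57-fold more frequent (36 windows against 14, adjusted exact p = 0.00548). Ohler 6 was 5.00-fold (15 windows against 3, adjusted exact p = 0.0129) and the Su(Hw) core 3.8-fold (19 against 5, adjusted exact p = 0.0129), each on few windows. The TATA box was 1.56-fold more frequent (adjusted exact p = 0.00548) and the E-box CATATG 1.37-fold (adjusted exact p = 0.0303). The GAGA, initiator, CAGCTG and Zelda elements did not pass the test, with folds of 0.962, 0.992, 0.953 and 1.2; against shuffled windows CAGCTG (3.09-fold, adjusted exact p = 8.24e-13), GAGA (1.74-fold, 7.05e-06) and the initiator (1.21-fold, 0.0393) were higher. Ohler 6 did not pass without replicate 2 (1.62-fold, 13 windows against 8) and was 11-fold without replicate 3, on 11 windows against 1. The TATA box and the Su(Hw) core did not pass without replicate 3 (1.07-fold and 1.46-fold), where GAGA was lower (0.751-fold, adjusted exact p = 0.0242), as in the stronger peaks (0.643-fold, 0.0132). CATATG lost its call with the flank 1000 bp away (1.21-fold, adjusted exact p = 0.281) and in the stronger peaks (1.34-fold, 0.167). On the 1446 stronger peaks, with fewer windows, Ohler 1 (3-fold, adjusted exact p = 0.132) and the Su(Hw) core (3.33-fold, 0.138) did not pass at folds near those of all peaks. The TATA box (1.16-fold) and the Su(Hw) core (1.58-fold) did not pass with the distant flank (adjusted exact p = 0.398 each), nor did Ohler 6 (2.14-fold) and the TATA box (1.23-fold) against shuffled windows (0.146 each).

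Among all 8192 7-mers, 451 were more frequent at summits and 509 less frequent. Against shuffled windows these numbers were 182 and 72. The 1534 peaks at protein-coding starts alone gave 91 and 78 against their flanks, an alternative added after seeing the data, and 13 and 0 against unbound starts. The first against the flanks of all peaks was ATCGATA, in 165 windows or 5.71% against 1.21% (4.71-fold, exact two-sided McNemar test, adjusted exact p = 9.91e-19), followed by CTATCGA (4.29% against 0.622%) and ACTATCG (3.8% against 0.553%). The AT-rich AAAATAT (11.8% against 6.29%), TATTTAA, AAATATT, TTTAAAA and AAATAAT came next by p. None of these passed against unbound starts, and only AAAATAT and AAATATT passed against shuffled windows. A separate sequence, AACACTG, was present in 3.53% against 1.07%. The lower 7-mers included CCTCCTC (0.242% against 2.42%) and CACACAC (3.01% against 7.19%). CACACAC turned against shuffled windows (3.01% against 1.24%, adjusted exact p = 0.000307), and CCTCCTC did not pass there (0.959) or against unbound starts (0.471). Summit windows had a GC content of 37.1% ± 8.74 (SD over peaks) and flanking windows 43.4% ± 10.1, and the windows of background regions 42.8% ± 10.2. ATCGATA was concentrated at gene starts, in 154 of 1608 windows there (9.58%) and 11 of 1284 elsewhere (0.857%; odds ratio 12.3, two-sided Fisher's exact p = 4.05e-28). The flanking windows of the peaks elsewhere held it in 0.701%. It was in 3.32% of the strongest 723 peaks (flanks 0.830%) and 5.39% of the weakest 723 (flanks 1.80%). This difference, in a comparison not fixed beforehand, did not pass the test (odds ratio 0.602, two-sided Fisher's exact p = 0.0705). Against the starts of unbound genes at matched distances (two-sided Fisher's exact tests on 1534 windows), DRE (1.74-fold, 4.89% against 2.80%, adjusted exact p = 0.00827), Ohler 7 (3.12-fold) and CGATA (1.44-fold) were more frequent, while the TATA box (0.582-fold, adjusted exact p = 0.00452) and the initiator (0.633-fold, adjusted exact p = 8.99e-05) were less frequent. Ohler 6 (1.08-fold, adjusted exact p = 1), Ohler 1 (1.52-fold, 0.283), the Su(Hw) core (1.6-fold, 0.696) and CATATG (1.25-fold, 0.503) did not pass there.

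**Figure D4:**
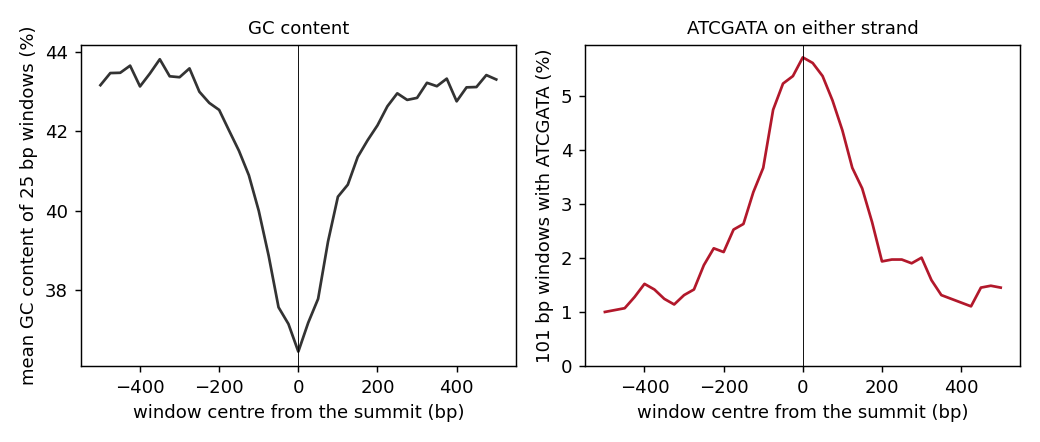
Mean GC content of 25 bp windows (left, percent) and share of 101 bp windows with ATCGATA on either strand (right, percent) by distance of the window centre from the summit (horizontal, bp), over 2892 thresholded peaks. GC content falls to 36.4% at the summit, where ATCGATA reaches 5.71%.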

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

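The counts in this part were made after the lists had been seen, and no test was run on them. Regions on dm3 sequences outside the 6 chromosome arms, which no comparison above used, stood out because the dm6 lists hold none there. The dm3 lists held 72 such regions in the pooled list, 99 in replicate 2 and 66 in replicate 3. The strongest lay on the unplaced sequence Uextra, with rank 1843 and a signal of 86.4 in the pooled list, and 3 such regions were in the thresholded dm3 list.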

How the results depend on the processing

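The shuffled windows, the null drawn from each replicate's own regions, the peak ranks of named genes in each replicate, the lists with CG1792 left out and the peaks at starts against their flanks were chosen after the result was seen. Replicate overlap, the promoter share against both backgrounds, and the cytoplasmic ribosomal protein and insulator lists kept their direction under each alternative, the insulator list losing its call in 2 of them. Depth is unknown, so what depth limits could not be examined, and the control alignment behind the calls was not analysed here. No paired analysis was possible because the samples form only 1 group. The causes of the changes below were not tested, except that the stronger 1446 peaks, the 1534 peaks at starts (also those set against unbound starts) and the genes with a pooled region leave fewer windows or genes by construction.

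The replicate correlation was 0.704 in the stronger peaks and 0.782 as Pearson's r of log2 signals. The promoter signal ratio was 1.01 with 250 bp and 1.02 to 1.07 with a replicate left out, and the X odds ratio was 0.907 with 1000 bp. Lists past the threshold fell from 8 to 5 with 250 bp, 4 in the stronger peaks, 1 among genes with a pooled region and 5 with the nearest start only. With 250 bp the call was lost for mitochondrial ribosomal proteins (odds ratio 1.99), ZAD (3.50) and heat shock (2.99), and muscle turned (0.614). With 1000 bp it was lost for mitochondrial ribosomal proteins (1.66) and ZAD (3.04), and proteasome (0.864), signalling (1.27) and muscle (0.880) turned. In the stronger peaks the odds ratios were 1.94 for mitochondrial ribosomal proteins, 3.81 for insulator, 2.81 for ZAD and 3.05 for both Polycomb and heat shock genes, all without a call; replication genes gained one (3.05), and proteasome (0.810), respiratory chain (1.08) and muscle (0.972) turned. Among genes with a pooled region they were 1.18 for mitochondrial ribosomal proteins, 3.44 for insulator, 3.30 for ZAD, 2.33 for Polycomb, 3.67 for heat shock, 0.211 for chemoreceptor and 0 for cuticle genes, all without a call, and proteasome turned (0.914). With the nearest start only, ZAD (3.89) and heat shock (2.70) lost the call, and mitochondrial ribosomal proteins (0.764), proteasome (0.568) and signalling (1.22) turned. With CG1792 left out 5 lists passed, and ZAD (3.03), heat shock (2.85) and mitochondrial ribosomal proteins (1.99) did not.

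With each replicate left out, odds ratios ran from 0.897 to 1.02 for proteasome, 1.02 to 1.07 for respiratory chain, 1.06 to 1.11 for signalling, 0.747 to 1.43 for muscle, 1.497 to 2.45 for heat shock, 1.25 to 2.40 for splicing factors, 1.84 to 2.60 for translation factors, 1.83 to 2.89 for replication and 2.72 to 3.78 for ZAD genes. The 451 7-mers became 843 with 100 bp on each side, 226 in the stronger peaks, 91 in the peaks at starts, 13 in the same peaks against unbound starts and 182 against shuffled windows, while the 509 lower ones became 1023, 212, 78, 0 and 72, and the 8 elements became 5 with the distant flank, 5 in the stronger peaks, 5 in the peaks at starts, 3 against unbound starts and 9 against shuffled windows. Elements that had not passed the test turned in direction. With 100 bp on each side these were GAGA (1.02), initiator (1.06), CAGCTG (1.08) and Zelda (0.875); with the distant flank, GAGA (1.16) and initiator (1.04); in the peaks at starts, CAGCTG (1.10) and Zelda (0.5), where the TATA box, the Su(Hw) core and CATATG lost their calls; against unbound starts, CAGCTG (1.01) and Zelda (0.308); against shuffled windows, GAGA (1.74), initiator (1.21) and CAGCTG (3.09), which all gained a call. With a replicate left out, initiator ran from 0.918 to 1.01 and Zelda from 0.524 to 0.900. The TATA box, which had passed, turned against unbound starts (0.582).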

Other observations

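The comparison of ribosomal protein genes with 6 other housekeeping lists, the shuffled windows, the relatives of ATCGATA at unbound starts, and the comparisons of head-to-head genes, symbol families and ribosomal protein windows were chosen after the result was seen. Genes whose start lies head to head with that of a neighbour were bound in 1083 of 3815 cases (28.4%), against 898 of 10130 other genes (8.86%; odds ratio 4.08, two-sided Fisher's exact p = 1.15e-171). Background regions, counted at any start within 500 bp, marked 54.4% and 37.3% of the same genes (odds ratio 2.01). With each summit given to its nearest start only, the odds ratio of the peaks was 2.01 (15.7% against 8.51%). Background regions were not counted by nearest start, so that value cannot be set against theirs. Of 75 symbol families with at least 10 genes, 6 were bound more often than other genes and 7 less often. The higher families beyond RpL, RpS and mRpL were the Mediator genes (MED, 9 of 25, odds ratio 3.41, adjusted exact p = 0.0404), genes of glycosylphosphatidylinositol anchor synthesis (PIG, 8 of 21, odds ratio 3.73, adjusted exact p = 0.0404) and genes with the prefix pre (10 of 24). A summit can mark several genes, so neighbouring members of a family are not independent. Peaks shared within families, the pre genes included, were not counted. The odorant-binding Obp genes (1 of 51, adjusted exact p = 0.0443) and the cytochrome P450 Cyp genes (4 of 85, adjusted exact p = 0.0443) were bound less often, as were the histone His genes (2.61%), where the bound members were His4r, His2Av and His3.3B, single genes outside the repeated cluster, and reads of the cluster's near-identical copies are uncertain.

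The peaks at ribosomal protein starts were compared with the other 1479 peaks at protein-coding starts. ATCGATA was present in 16 of 55 windows (29.1%) against 9.33%, and ACTATCG in 14 (25.5%) against 5.95% (exact two-sided test, adjusted exact p = 0.0207 and 0.00451). The smallest p was that of CGTTTCC, in 11 of the 55 (20%) against 1.08% (adjusted exact p = 3.11e-06), and 30 of 8192 7-mers were more frequent and 0 less frequent. With only 55 windows a lower share could hardly pass adjustment over 8192 7-mers, so nothing is concluded from the 0. The median signal was 127.4 at ribosomal protein starts and 101.3 at the others.

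Cytoplasmic ribosomal protein genes had the highest odds of binding among the lists. The mere presence of a pooled region at their starts was argued against as the whole cause by an odds ratio of 5.51 among genes with such a region, down from 10.3 among all genes. Such a region was found for 83 of the 88, against 7414 of all 13945 genes, so its presence stays open for a part. The thresholded peaks were the strongest of the same pooled regions. A generally higher signal at these starts would raise the share past that higher cut too, so easier detection of this kind cannot be told apart and stays open. A property of housekeeping promoters in general was argued against as the whole cause by an odds ratio of 6.48 (95% interval 3.8 to 11.2) against the 329 genes of the mitochondrial ribosomal, translation, proteasome, respiratory chain, splicing and replication lists, of which 20.4% were bound (odds ratio 1.56, 95% interval 1.17 to 2.06, against all other genes). Shared or neighbouring starts were argued against by an odds ratio of 12.75 with each summit given to its nearest start, where 52 of 88 were bound. The high transcription of these genes, which may raise signal in such assays, stays open and was not tested, since no expression measure was used here; a preference of CG1792 for these promoters is a hypothesis, and the design gives no biological contrast.

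The 7-mer ATCGATA and its overlapping relatives were more frequent at summits than in flanking windows over all peaks. Away from starts ATCGATA was in 0.857% of summit windows and 0.701% of flanking windows, so its excess lay mainly at starts. Base composition was argued against by an 8.25-fold excess over windows shuffled with their dinucleotides kept. Position at gene starts was examined in the 1534 peaks there against unbound starts at the same distances, with a 2-fold excess set in advance for ATCGATA as excluding it. For its relatives a stricter rule, a lower 95% bound over 2, was written after the result was seen. By that rule, position was argued against as the whole cause for ACTATCG by a 3.4-fold excess (102 of 1534, 6.65% against 1.956%, 95% interval 2.28 to 5.08, adjusted exact p = 7.67e-07). ACTATCG was also the first of all 7-mers in this comparison. Position stays open for ATCGATA, whose excess was 1.86-fold (10% against 5.41%, adjusted exact p = 0.00287), and for CTATCGA (2.33-fold, 95% interval 1.68 to 3.23) and AACTATC (2.875-fold, 1.82 to 4.55), whose intervals reach below 2. The kind of promoter that CG1792 occupies was not examined apart from position and stays open. No biological explanation was tested.

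Among the 2892 strongest regions of each replicate, 969 had no partner within 100 bp in the other. A class of site in 1 library that differs strongly in promoter share was argued against by their shares, 52.6% in replicate 3 and 56.4% in replicate 2. The difference was −3.82 percentage points (95% interval −8.23 to 0.614). Classes that differ in sequence or kind of gene can have like promoter shares. The unpartnered regions were not compared in these, so a different class of site stays open. The rank threshold may account for part of the unpartnered regions, since 65.8% (1275 of 1938) had a partner somewhere in the other's complete list. This share lies between the 50% and 80% set in advance, so the rank threshold stays open. Their median rank was 2156 in replicate 2, against 1019 for partnered regions. No biological explanation was tested.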
